A study of Mus musculus with 12 samples.

How the data were processed

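Total RNA from dissected mouse cardiogenic regions was sequenced at 4 stages, with 3 libraries per stage. Per the labels' protocols the tissue went into TriZol and libraries were made by a standard Illumina preparation. The submitters' processing notes name STAR 2.5.0 (a spliced read aligner) and Cufflinks 2.2.1 (a transcript assembler) and the builds GRCm38 or mm10 and hg38, without a role for each. The deposited table holds whole-number read counts per gene and library, not normalised by the authors, with 48709 gene intervals per the file headers. The counting tool, its strand setting and the annotation release are not given in the sources used here. No label says that libraries came from separate litters or embryos, so p-values measure only the spread between these samples, which may be technical. Replicates of a stage differed by more than counting noise (mean chi-square of 8.35 to 203 per gene), and each counted as 1 sample.

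Gene intervals were matched to GENCODE release M21 (GRCm38) for types and strands: 42778 had an identical interval and strand, 5645 were matched by symbol and overlap and 286 were not matched. Coordinates are those of the deposited table. The table repeats some names, on 238 intervals, each tested on its own. In all 21428 intervals overlap another. Of 1983 gene intervals lying inside another on the same strand, the enclosing interval had at least the count of the enclosed one in all libraries in 99.6%, and of 1942 on opposite strands in 99.1%, beside 82.2% and 80.0% with shuffled partners. Counts therefore may include exonic and intronic reads of either strand, and overlapping or antisense genes share reads. The 37 genes of the mitochondrial chromosome had 0 counts and mitochondrial genes were not analysed here. Small structural RNAs took 16.6% to 24.1% of the 56574386 to 122785175 counts of a library. Intervals and floors given for counts cover counting error only.

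Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr left 28846 genes, TMM factors ran from 0.913 to 1.07, and 1 quasi-likelihood model (robust glmQLFit) with a mean per stage was fitted to all 12 libraries, with a common dispersion of 0.0362. E8.5 was compared with E8, E9.5 with E8.5, E14 with E9.5 and E14 with E8, each by a quasi-likelihood F-test, and the 4 stages were tested together. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. SE are those of the edgeR log2 fold changes, and CPM use the TMM-scaled library sizes. Gene lists were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over all lists and comparisons together, and again with a correlation estimated from the residuals. The 32 lists covered core cardiac transcription factors, second heart field and progenitors, sarcomere, calcium handling and ion channels, chamber and conduction patterning, fatty acid oxidation, oxidative phosphorylation (nuclear), glycolysis and glucose uptake, cell cycle, primitive streak and early mesoderm, pluripotency and epiblast, DNA methylation machinery, Hox genes, retinoic acid pathway, BMP pathway, imprinted growth genes, named long non-coding RNAs, epicardium, fibroblast and matrix, endothelium and endocardium, smooth muscle and pericyte, valve mesenchyme, primitive erythroid globins, erythroid cells, macrophage and leukocyte, endoderm and epithelium, visceral endoderm and liver, neural tube, neural crest and glia, somite and skeletal muscle, surface ectoderm and lung epithelium. Of their genes 34 lay below the filter and 3 (Hbb-b1, Hbb-b2 and Ahsp, all of the erythroid list) were not matched. Long non-coding RNAs were paired with a coding gene on the other strand, head to head, with starts at most 2000 bp apart, and correlated by 100000 permutations of the partners. Python 3.11, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and figures.

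The genes named were set by a rule. Per interval it took (a) the 8 largest positive and 8 largest negative log2 fold changes among called genes with all 3 libraries of one stage above all 3 of the other and a mean of at least 10 CPM in the higher stage. Genes without a symbol, Rik, Gm-number, LOC, mitochondrial, ribosomal protein and histone genes and pseudogenes were left out. It also took (b) members of the lists, called ones with the largest change first, (c) T, Dnmt3b, Dnmt3a, Mesp1, Isl1, Nkx2-5, Tnnt2, Myh6, Myh7, Nppa, Hand2, Hand2os1, Xist, Ddx3y and Eif2s3y, and (d) the 5 divergent pairs with the smallest sum of adjusted p ranks. The result of 1 gene is not reported here. The groups, tests, lists, this rule and most alternatives were set before the data were examined. These alternatives were RLE and upper-quartile factors in place of TMM, other filters, a replicate block, glmTreat, fits of the compared stages alone, DESeq2 1.42.0, globin, mitochondrial and ribosomal RNA genes left out, other pair distances and each library left out in turn. Chosen after seeing the data were offsets adjusted for gene span (per library, a lowess curve of log2 CPM against interval length with a span of 0.3), the same without E8.5 replicate 3, only genes whose interval overlaps no other, small structural RNAs left out, and pairs whose intervals do not overlap.

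The model was tested on counts simulated from these data's means and library sizes, with 200 genes changed 1.5-, 2- or 4-fold. Called in the right direction were 21.5%, 56.9% and 90.3% for E8.5 against E8 (28224 genes tested), 28.4%, 65.6% and 86.4% for E9.5 against E8.5 (28250), 16.4%, 60.0% and 78.1% for E14 against E9.5 (28248) and 19.7%, 62.7% and 69.7% for E14 against E8 (28295). Of 28621 unchanged genes 9, 7, 2 and 5 were called in the same order. These omit false calls from a deviant library or a gene-span trend. The recovery required at the largest fold was lowered to 60% after a first run missed a higher one. For pairs, 300 simulated with a true r of 0.5 gave 0.533 and 300 unrelated ones 0.0120.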

Results

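RNA was sequenced from dissected cardiogenic regions of mouse embryos, the tissue that forms the heart, at embryonic days 8, 8.5, 9.5 and 14 (E8, E8.5, E9.5 and E14). Each stage had 3 libraries made from total RNA, 12 in all. The libraries hold RNA of whole dissected tissue, so changes within a cell type and changes in the mix of cells cannot be told apart. Total counts ran from 101231014 to 122785175 per library at E8, 101202593 to 111404849 at E8.5, 73056001 to 90620692 at E9.5 and 56574386 to 97187372 at E14. The series title concerns a long non-coding RNA that acts on the mesodermal programme and on the DNA methyltransferase DNMT3B. The comparisons covered the 3 intervals between neighbouring stages and the whole span. Xist, the RNA of the inactive X chromosome, ran from 92.9 to 268 CPM (counts scaled to library size) over the 12 libraries, and the Y-linked genes Ddx3y (20.9 to 48.0 CPM) and Eif2s3y (10.5 to 23.0 CPM) had counts in all 12. Globin genes took 0.06% of the counts of each E8 library and 1.91% to 6.03% at E14. The first principal component of log2 CPM held 59.1% of the variance and placed the E8 libraries at -80.5 to -76.8, E8.5 replicates 1 and 2 at -60.6 and -63.4, the E9.5 libraries at -17.3 to 4.05 and the E14 libraries at 149 to 159. E8.5 replicate 3 lay at -83.3, beyond the E8 libraries. On the fourth component, with 5.1% of the variance, it stood apart from all other libraries, at 77.4 beside -32.5 to 14.9.

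Dnmt3b, one of the de novo DNA methyltransferases (GRCm38, chromosome 2, 153649450 to 153687730, plus strand), fell at each interval after E8.5: its level was 40.1 ± 0.829 CPM at E8, 41.3 ± 12.8 at E8.5, 20.8 ± 2.97 at E9.5 and 6.91 ± 0.610 at E14 (mean ± SD, n = 3 libraries). On the log2 scale it fell by 0.99 ± 0.18 (SE) from E8.5 to E9.5 (adjusted p = 0.00167, edgeR's quasi-likelihood test) and by 1.58 ± 0.19 from E9.5 to E14 (adjusted p = 2.87e-05, edgeR). E8 and E8.5 were not separated (0.04 ± 0.18, edgeR adjusted p = 0.899), and E8.5 replicate 3 had 55.6 CPM beside 30.8 and 37.6 in replicates 1 and 2. Without that library the values were -0.27 ± 0.12 for E8.5 against E8 and -0.69 ± 0.12 for E9.5 against E8.5. Dnmt3a, the other de novo enzyme (GRCm38, chromosome 12, 3806007 to 3914443, plus strand), moved the opposite way, from 61.4 ± 1.36 CPM at E8 to 126 ± 6.67 at E14 (1.04 ± 0.12, edgeR adjusted p = 1.52e-05), with the rise called between E8.5 and E9.5 (0.67 ± 0.12). Of the other genes of DNA methylation, the oxidase gene Tet3 fell between E8.5 and E9.5 (-0.77 ± 0.20, and -0.48 ± 0.15 with an adjustment for gene span), a call that ended without E8.5 replicate 2 (edgeR adjusted p = 0.0553) and in a fit of these 2 stages alone (0.0589). Between E9.5 and E14 Tet2, a 5-methylcytosine oxidase, rose (1.08 ± 0.10) and Uhrf1, the partner of the maintenance enzyme, fell (-0.90 ± 0.08). The list of DNA methylation machinery had 0 of 11 measured members called by edgeR between E8 and E8.5 (0 adjusted over the list alone, median 0.19). Between E8.5 and E9.5 1 rose and 5 fell (1 and 7 adjusted over the list alone, median -0.32), and between E9.5 and E14 3 rose and 4 fell (5 and 4 adjusted over the list alone). In the last interval its median was 0.05 and its mean -0.12, with opposite signs. The lowest camera adjusted p of the list over the 4 comparisons was 0.130. T (Brachyury), the T-box factor of the primitive streak (GRCm38, chromosome 17, 8434423 to 8442496, plus strand), was near the floor of detection, with 35 to 55 counts per library at E8, 19 to 42 at E8.5, 2 to 9 at E9.5 and 12 to 17 at E14. It fell between E8.5 and E9.5 (-1.84 ± 0.46, edgeR adjusted p = 0.00963, and 0.0552 in the fit of these 2 stages alone) and rose between E9.5 and E14 (1.46 ± 0.48, edgeR adjusted p = 0.0251). The rise lost its call when E9.5 replicate 2 or 3 or any E14 library was left out (edgeR adjusted p = 0.0512 to 0.0779). Mesp1, the first marker of cardiac mesoderm, had 9 counts over the E8.5 libraries, 458 at E9.5 and 0 at E14, at least 134-fold lower at E14 than at E9.5 against a floor of 3 counts over the group.

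**Figure D1:**
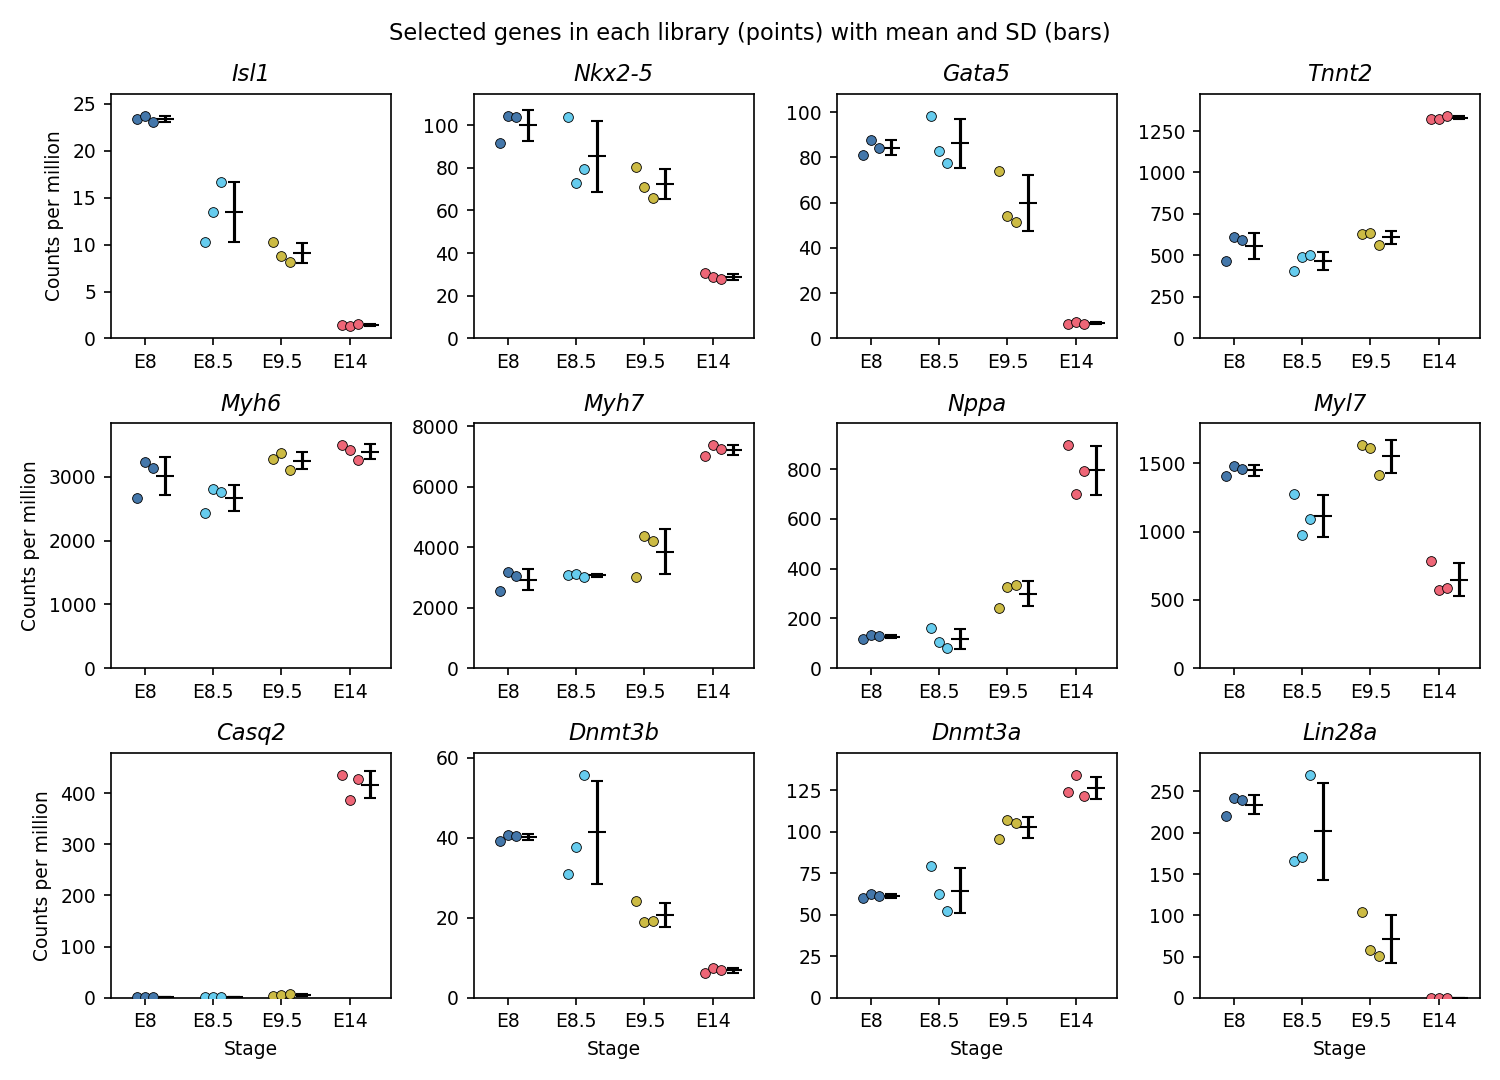
CPM (y axis) of 12 genes at the 4 stages (x axis), with 1 point per library and bars for the mean and SD of the 3 libraries. Tnnt2 stood at 556 ± 79.3 CPM at E8 and 1330 ± 10.4 at E14, and Isl1 fell from 23.4 ± 0.349 to 1.42 ± 0.0747.

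The first interval, E8 to E8.5, spans the forming heart tube. Isl1, the LIM-homeodomain factor of second heart field progenitors (GRCm38, chromosome 13, 116298281 to 116309689, minus strand), fell by 0.79 ± 0.14 on the log2 scale, from 23.4 ± 0.349 to 13.5 ± 3.20 CPM. Of the genes taken by the fixed rule, the 8 with the largest rise began with Apoc2, an apolipoprotein of yolk sac endoderm and liver (7.12 ± 1.41), Bnc2, a zinc finger protein of mesenchyme (1.92 ± 0.22), and Arhgap6, a GTPase-activating protein (1.31 ± 0.26). The others were the nucleotide-sugar receptor P2ry14 (1.26 ± 0.25), the neuregulin receptor Erbb4 (1.22 ± 0.25), the sarcoglycan Sgcz (1.20 ± 0.23), the scaffold protein Pdzk1 (1.13 ± 0.18) and the chondroitin synthase Chsy3 (1.07 ± 0.21). Beside Isl1, the largest falls were in Mocs1, an enzyme of molybdenum cofactor synthesis (-0.88 ± 0.11), the potassium channel partner Kcnip1 (-0.82 ± 0.17) and the long non-coding RNA Platr30 (-0.76 ± 0.12). The others were the long non-coding RNA Platr25 (-0.63 ± 0.08), the microRNA precursor Mir3091 (-0.69 ± 0.12), the small nucleolar RNA Snord43 (-0.64 ± 0.10) and the zinc finger gene Zfp213 (-0.62 ± 0.09). Values in brackets after gene names are log2 fold changes with their SE, with n = 3 libraries per stage. By edgeR's quasi-likelihood test the adjusted p of these 16 genes ran from 0.0145 to 0.0488. Of the genes of heart muscle named by the rule, none passed: the homeobox factor Nkx2-5 (-0.23 ± 0.12), troponin T gene Tnnt2 (-0.25 ± 0.12), the myosin heavy chains Myh6 (-0.18 ± 0.10) and Myh7 (0.07 ± 0.14), the natriuretic peptide Nppa (-0.12 ± 0.21), Hand2 (-0.32 ± 0.09) and the long non-coding RNA upstream of it, Hand2os1 (0.11 ± 0.21). Without E8.5 replicate 3 Hand2 (-0.29 ± 0.09, edgeR adjusted p = 0.0296) and Hand2os1 (0.34 ± 0.10, 0.0212) were called. Apoc2 rested on E8.5 replicate 3, at 51.5 CPM beside 3.17 and 1.12, and stood at 3.97 ± 0.46 without that library. The intervals of Apoc2, P2ry14, Pdzk1, Mir3091, Snord43 and Zfp213 overlap those of other genes (Gm44805, Med12l, Gpr89, Rps21, Rpl3 and Gm26695) with counts 0.558 to 38.3 times their own, so that reads of the overlaps cannot be told apart. The same holds, at 0.518 to 4.54 times, for Apoa4, Afp, Hoxc6, Nppa, Cox6a2, Fabp3, Nr2f1, Nr2f2, Pln, Nkx2-1, Gja5, Hoxa11 and Xist. With library offsets adjusted for gene span the values were 0.79 ± 0.15 for Arhgap6, 0.61 ± 0.15 for Erbb4, 0.59 ± 0.15 for Sgcz and 0.67 ± 0.14 for Chsy3, that of Kcnip1 grew to -1.23 ± 0.25, and 8 of the 16 genes lost their call (edgeR adjusted p = 0.0503 to 0.0779).

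In all, 257 genes rose and 84 fell between E8 and E8.5 among the 28846 tested (edgeR). Of these 206 and 57 were protein-coding and 25 and 8 long non-coding, and 8106 genes had an unadjusted p under 0.05. The coding genes that rose were long, with a median interval of 104 kb beside 9.5 kb for those that fell and 23.3 kb for all tested. With the span adjustment 69 rose and 49 fell, so that 58.5% of the calls were rises in place of 75.4%. With small structural RNAs left out of the library sizes and the tests 659 rose and 480 fell. The counts changed with the libraries: genes higher and lower numbered 32 and 11 without E8 replicate 1, 10 and 4 without E8 replicate 2, 0 and 0 without E8 replicate 3 (5398 at an unadjusted p under 0.05 in edgeR) and 68 and 14 without E8.5 replicate 2. They were 161 and 52, 5 and 5 and 41 and 14 without E9.5 replicates 1, 2 and 3, and 9 and 11, 4 and 6 and 4 and 7 without E14 replicates 1, 2 and 3. Libraries of E9.5 and E14 enter this comparison through the shared filter, scale factors and estimate of the spread. Without E8.5 replicate 3, 4212 genes rose and 4653 fell, and these included all 257 and 84. All 16 genes named by the rule lost their call without E8 replicate 3 (edgeR adjusted p = 0.136 to 0.217) and all 16 kept it without E8.5 replicate 3. By the other libraries, left out in turn, the number of the 16 that lost their call (and the edgeR adjusted p) was 11 (0.0532 to 0.0743) for E8 replicate 1, 14 (0.0508 to 0.212) for E8 replicate 2, 4 (0.0527 to 0.0668) for E8.5 replicate 1 and 10 (0.0521 to 0.124) for E8.5 replicate 2. For the E9.5 libraries 1, 2 and 3 it was 4 (0.0502 to 0.0542), 13 (0.0578 to 0.0816) and 9 (0.0547 to 0.0660), and for the E14 libraries 1, 2 and 3 11 (0.0509 to 0.0593), 13 (0.0583 to 0.0755) and 13 (0.0692 to 0.0840) (edgeR). All 22 called genes named for this interval lost their call in a fit of these 2 stages alone (edgeR adjusted p = 0.0643 to 0.184) and against a log2 fold change of 1 (glmTreat, edgeR), 10 did without a filter on low counts, 4 with upper-quartile and 2 with RLE factors, and 3 without globin, mitochondrial and ribosomal RNA genes. DESeq2 called 2361 genes higher and 2075 lower.

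Among the gene lists, markers of visceral endoderm and liver stood apart between E8 and E8.5: 2 of 15 rose, 0 fell and 13 did not pass (13 and 0 adjusted over the list alone). The visceral endoderm and liver list had a median log2 fold change of 4.0 and a camera adjusted p = 6.69e-06 (adjusted p = 0.456 with an estimated correlation). The members called were Apoc2 and Apoa4 (6.0 ± 1.15), both apolipoproteins. Cubn, the endocytic receptor of the yolk sac, was at 470 CPM in E8.5 replicate 3, 46.2 and 16.9 in replicates 1 and 2, and 5.39 at most at E8. Afp, the fetal serum protein, was at 246, 25.5 and 5.66 CPM in replicates 3, 1 and 2 and 1.67 at most at E8. Without E8.5 replicate 3 the median of this list was 2.31 and 7 members rose (edgeR). Of the erythroid genes, 0 of 14 rose, 0 fell and 14 did not pass (4 and 0 adjusted over the list alone). The erythroid cells list had a median of 0.87 and a camera adjusted p = 0.00109 (adjusted p = 0.533 with an estimated correlation). Of the Hox genes, which set position along the body axis, 2 of 26 rose, 0 fell and 24 did not pass (7 and 0 adjusted over the list alone). The Hox genes list had a median of 1.1 and a camera adjusted p = 0.0229 (adjusted p = 0.456 with an estimated correlation), and the called members were Hoxc4 (3.11 ± 0.64) and Hoxc6 (2.83 ± 0.57), at 0.184 ± 0.0255 and 0.190 ± 0.0367 CPM at E8.5. Of the fibroblast and matrix genes, 2 of 18 rose, 0 fell and 16 did not pass (6 and 0 adjusted over the list alone), with the collagens Col6a3 (1.60 ± 0.32) and Col1a1 (0.85 ± 0.18) called. The fibroblast and matrix list had a median of 0.23 and a camera adjusted p = 0.0220 (adjusted p = 0.456 with an estimated correlation). Bmp6, a ligand of the BMP pathway, rose as well (0.83 ± 0.17), the only call of its list, for which 1 of 16 rose and 0 fell (1 and 2 adjusted over the list alone), median -0.15, camera adjusted p = 0.235. The highest edgeR adjusted p of these 6 called genes was 0.0492. All 6 lost their call without E8 replicate 1, 2 or 3, without E9.5 replicate 2 and without each E14 library (edgeR adjusted p = 0.0561 to 0.217). Other calls ended without E8.5 replicate 1 (Col1a1, Col6a3, Hoxc4 and Hoxc6), E8.5 replicate 2 (these 4 and Bmp6), E9.5 replicate 1 (Apoa4, Col1a1, Col6a3 and Hoxc6), E9.5 replicate 3 (Apoa4, Bmp6, Col6a3 and Hoxc6) and with the span adjustment (all 6), with edgeR adjusted p = 0.0502 to 0.129. Apoa4 stood at 3.62 ± 0.53 without E8.5 replicate 3.

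From E8 to E8.5, of the second heart field and progenitor genes, 0 of 16 rose, 1 fell and 15 did not pass (0 and 3 adjusted over the list alone), the called member being Isl1. The second heart field and progenitors list had a median log2 fold change of -0.31 and a camera adjusted p = 0.00440 (adjusted p = 0.344 with an estimated correlation). The lists of sarcomere (median -0.18), chamber and conduction patterning (-0.16), nuclear oxidative phosphorylation (-0.23), glycolysis and glucose uptake (-0.18) and cell cycle (-0.18) were called lower by camera, with adjusted p from 7.04e-04 to 0.0185 (adjusted p = 0.456 to 0.590 with an estimated correlation). No member of these 5 lists passed edgeR's test over all genes, and adjusted over the list alone 0, 4, 2, 1 and 0 of them were lower. Calcium handling and ion channel genes were called higher as a list, and 0 of 20 rose, 0 fell and 20 did not pass (4 and 0 adjusted over the list alone). The calcium handling and ion channels list had a median of 0.20 and a camera adjusted p = 0.0220 (adjusted p = 0.533 with an estimated correlation). Without E8.5 replicate 3 the calls of second heart field (camera adjusted p = 0.0686), sarcomere (0.398), chamber patterning (0.112), Hox genes (0.112) and fibroblast and matrix (0.0596) ended. Also without it 11 endoderm and epithelium genes fell (median -0.90, camera adjusted p = 5.06e-04, and adjusted p = 0.716 with an estimated correlation over all libraries), 15 cell cycle genes fell and 1 rose (median -0.31), 5 fibroblast genes rose (median 0.50) and 10 calcium handling genes rose (median 0.37). The calcium handling call also ended without E8.5 replicate 1 (camera adjusted p = 0.108), without E8.5 replicate 2 (0.117) and with the span adjustment (0.442). The cell cycle call ended without E8.5 replicate 2 (camera adjusted p = 0.0838), and that of fibroblast and matrix without E8 replicate 1 (0.0895) and with the span adjustment (0.0926). In the lists that were not called, retinoic acid (median 0.05), macrophage (0.10) and named long non-coding RNAs (0.11) had positive medians and a lower camera direction, and neural crest (median -0.00339, mean 0.0255) and fatty acid oxidation (-0.0316 and 0.00805) a median and mean of opposite sign.

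**Figure D2:**
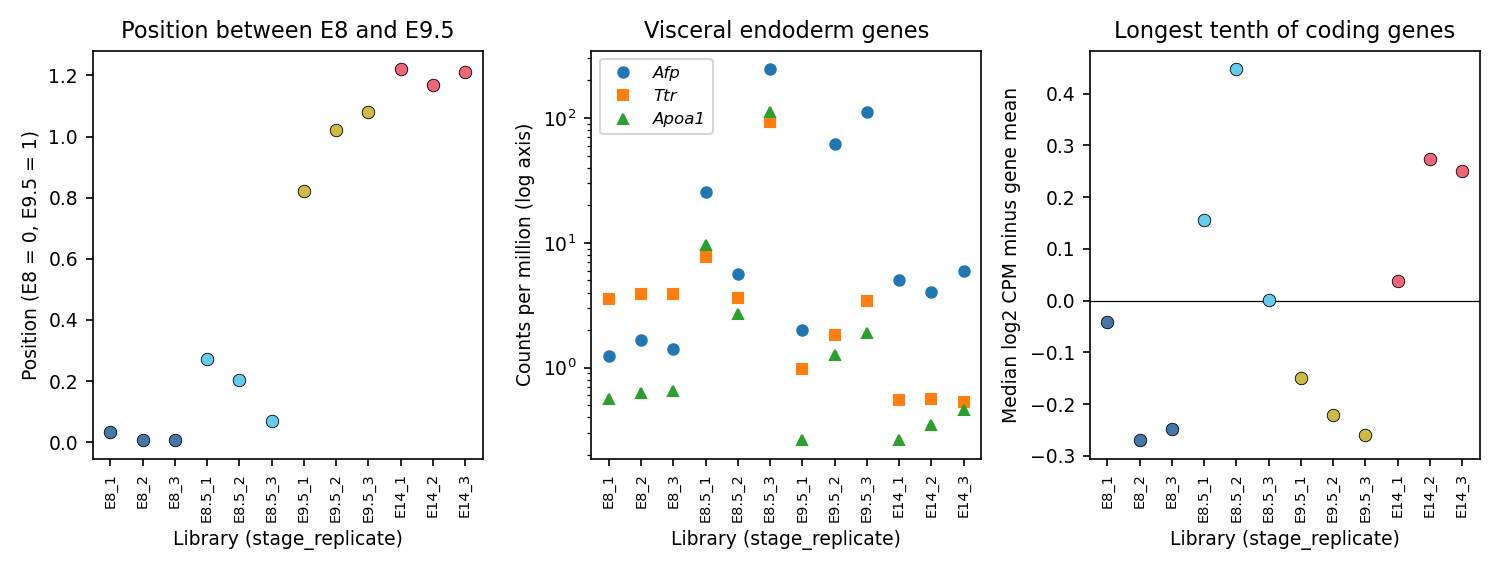
The 12 libraries (x axes, 3 per stage, 1 point per library) by their position between the mean of E8 (0) and of E9.5 (1) over 9860 genes that differ between these stages (left), by the CPM of 3 visceral endoderm genes on a log axis (middle) and by the median log2 CPM of the longest 10% of coding genes relative to each gene's mean (right). At the right E8.5 has 0.001 to 0.447, E9.5 -0.259 to -0.15 and E14 0.037 to 0.273.

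Between E8.5 and E9.5 the largest rises included epicardial and globin genes and the largest falls endoderm genes. Of the 8 genes with the largest rise by the fixed rule, Upk3b, a uroplakin of mesothelium (4.37 ± 0.62), and the T-box factor Tbx18 (3.39 ± 0.34) mark the epicardium, and the globins Hbb-y (4.19 ± 0.58) and Hba-a1 (3.19 ± 0.46) mark erythroid cells. The others were the growth factor gene Ptn (3.52 ± 0.53), the ephrin receptor Epha3 (3.52 ± 0.56), the integrin Itga4 (3.33 ± 0.50) and Trim30a (3.66 ± 0.32). The 8 largest falls were in Apoc2 (-6.73 ± 1.40), Cubn (-5.63 ± 1.09), Apob (-5.57 ± 1.15), Apoa1 (-5.15 ± 1.24) and Ttr (-4.04 ± 1.06), which encode lipid and hormone carriers and a receptor of visceral endoderm and liver, and in the protease Tmprss2 (-4.40 ± 0.92), the protease inhibitor Spink1 (-4.31 ± 0.85) and the glucose transporter Slc2a2 (-3.79 ± 0.99). The highest adjusted p of the 16 genes was 0.0142 (edgeR). The E8.5 level of the falling genes rested on replicate 3: without that library the values were -3.60 ± 0.46 for Apoc2, -3.11 ± 0.37 for Cubn, -2.89 ± 0.45 for Apob and -2.40 ± 0.67 for Apoa1. They were -1.42 ± 0.42 for Ttr, -2.17 ± 0.21 for Tmprss2, -2.41 ± 0.27 for Spink1 and -1.23 ± 0.33 for Slc2a2, all still called by edgeR (highest adjusted p = 0.0217). Ttr lost its call without E9.5 replicate 2 (edgeR adjusted p = 0.0577), and Apoc2, Ttr and Slc2a2 share their interval in part with Gm44805, Gm16090 and 1700112D23Rik. Of the cardiac genes set by the rule, Nppa rose (1.36 ± 0.21), as did Hand2 (0.38 ± 0.09), and Isl1 fell further (-0.57 ± 0.14, and -0.36 ± 0.12 without E8.5 replicate 3). In a fit of these 2 stages alone the calls of Isl1, Tnnt2, Apoa1, Slc2a2 and Ttr ended (edgeR adjusted p = 0.0549 to 0.0735). Tnnt2 rose (0.38 ± 0.12, edgeR adjusted p = 0.0257), a call that ended without E8.5 replicate 1, E9.5 replicate 1 or E9.5 replicate 2 (edgeR adjusted p = 0.0635 to 0.0845). Myh6 (0.29 ± 0.10, edgeR adjusted p = 0.0505), Myh7 (0.33 ± 0.14), Nkx2-5 (-0.24 ± 0.12) and Hand2os1 (0.23 ± 0.21, and -0.01 ± 0.10 without E8.5 replicate 3) did not pass. Myh6 was called higher in 8 of the alternatives (0.34 ± 0.12, edgeR adjusted p = 0.0307, without E8.5 replicate 3) and Myh7 in 2. In all 5316 genes rose and 5343 fell of 28846 (edgeR), 498 and 732 of them long non-coding. The lower count was 3366 without E9.5 replicate 2 and 3416 without E9.5 replicate 3, and the fit of these 2 stages alone gave 3353 and 2746. By glmTreat (edgeR) 25 of the 70 called genes named for it were called.

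Metabolic and heart muscle lists were called over this interval as well. Of the nuclear genes of the respiratory chain, 18 of 20 rose, 0 fell and 2 did not pass (20 and 0 adjusted over the list alone). The oxidative phosphorylation list had a median log2 fold change of 0.80 and a camera adjusted p = 3.89e-10 (adjusted p = 0.456 with an estimated correlation). The largest rises in it were in Cox6a2, the muscle form of a cytochrome c oxidase subunit (2.02 ± 0.23), and Ndufa4 (0.94 ± 0.13). Of the fatty acid oxidation genes, 15 of 20 rose, 1 fell and 4 did not pass (16 and 1 adjusted over the list alone), led by the fatty acid-binding protein Fabp3 (1.19 ± 0.11) and the trifunctional enzyme subunit Hadhb (1.03 ± 0.12). The fatty acid oxidation list had a median of 0.68 and a camera adjusted p = 3.26e-06 (adjusted p = 0.456 with an estimated correlation). Of the sarcomere genes, 14 of 25 rose, 3 fell and 8 did not pass (17 and 4 adjusted over the list alone). The sarcomere list had a median of 0.38 and a camera adjusted p = 0.00107 (adjusted p = 0.456 with an estimated correlation). Myoz2, a Z-disc protein (3.20 ± 0.36), the ventricular light chain Myl2 (1.92 ± 0.20) and the cardiac troponin I gene Tnni3 (1.32 ± 0.16) rose, while titin, Ttn, fell (-1.40 ± 0.31, and -1.02 ± 0.33 with the span adjustment). With that adjustment and without E8.5 replicate 3 titin stood at -0.47 and was not called (edgeR adjusted p = 0.0929). Of the chamber and conduction patterning genes, 9 of 15 rose, 2 fell and 4 did not pass (10 and 2 adjusted over the list alone), led by the sinus node factor Shox2 (2.87 ± 0.20) and the atrial receptors Nr2f1 (2.22 ± 0.27) and Nr2f2 (1.60 ± 0.21). The chamber and conduction patterning list had a median of 0.40 and a camera adjusted p = 0.00200 (adjusted p = 0.456 with an estimated correlation). The interval of Shox2 lies in part within Rsrc1, whose count was 35.9 times its own. Of the cell cycle genes, 12 of 25 rose, 0 fell and 13 did not pass (12 and 0 adjusted over the list alone), for example the cyclin Ccnb2 (0.62 ± 0.11) and the survivin gene Birc5 (0.61 ± 0.10). The cell cycle list had a median of 0.29 and a camera adjusted p = 7.63e-05 (adjusted p = 0.533 with an estimated correlation). Of the pluripotency and epiblast genes, 1 of 12 rose, 8 fell and 3 did not pass (1 and 8 adjusted over the list alone). The pluripotency and epiblast list had a median of -1.26 and a camera adjusted p = 0.00949 (adjusted p = 0.456 with an estimated correlation). Fgf5 rose (2.32 ± 0.52), and L1td1 (-1.89 ± 0.35) and the Nodal co-receptor Tdgf1 (-1.74 ± 0.29) fell. For calcium handling 5 of 20 rose and 5 fell (6 and 5 adjusted over the list alone), median 0.06, camera adjusted p = 0.761. The phospholamban gene Pln (3.10 ± 0.39) and the potassium channels Kcnj3 (2.08 ± 0.35) and Kcnj2 (2.0 ± 0.23) rose, and the calcium channel Cacna1c fell (-1.13 ± 0.30, and -0.61 ± 0.19 with the span adjustment). The fall of Cacna1c lost its call without E8.5 replicate 2 (edgeR adjusted p = 0.0556) and without E9.5 replicate 3 (0.0546).

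From E8.5 to E9.5, of the epicardium genes, 9 of 11 rose, 1 fell and 1 did not pass (9 and 1 adjusted over the list alone), with Bnc1 (2.69 ± 0.37) behind Upk3b and Tbx18. The epicardium list had a median log2 fold change of 2.18 and a camera adjusted p = 4.81e-04 (adjusted p = 0.456 with an estimated correlation). Of the erythroid genes, 12 of 14 rose, 0 fell and 2 did not pass (12 and 0 adjusted over the list alone). The erythroid cells list had a median of 1.26 and a camera adjusted p = 9.72e-06 (adjusted p = 0.456 with an estimated correlation), and all 3 primitive erythroid globins rose (3 adjusted over the list alone, median 2.61, camera adjusted p = 0.00842, and adjusted p = 0.456 with an estimated correlation). Of the endoderm and epithelium genes, 0 of 14 rose, 14 fell and 0 did not pass (0 and 14 adjusted over the list alone). The endoderm and epithelium list had a median of -2.85 and a camera adjusted p = 6.69e-06 (adjusted p = 0.456 with an estimated correlation). The largest falls in it were in the hormone precursor Trh (-4.57 ± 0.78), the thyroid and lung factor Nkx2-1 (-4.33 ± 0.86, and -7.72 without E9.5 replicate 1) and Spink1. Of the visceral endoderm and liver genes, 2 of 15 rose, 9 fell and 4 did not pass (2 and 9 adjusted over the list alone). The visceral endoderm and liver list had a median of -2.65 and a camera adjusted p = 0.0427 (adjusted p = 0.716 with an estimated correlation). Albumin, Alb, rose there (5.76 ± 1.25). Without E8.5 replicate 3 that list had a median of -0.67 with 8 members lower and 2 higher (camera adjusted p = 0.0837), and without E9.5 replicate 1 a camera adjusted p = 0.437. Of the surface ectoderm genes, 6 of 10 rose, 0 fell and 4 did not pass (6 and 0 adjusted over the list alone), with the keratin Krt15 (3.29 ± 0.51) and the epidermal factor Grhl3 (2.63 ± 0.25) at the top. The surface ectoderm list had a median of 1.08 and a camera adjusted p = 0.0210 (adjusted p = 0.486 with an estimated correlation). Second heart field genes were not called as a list: 3 of 16 rose and 7 fell (3 and 9 adjusted over the list alone), median -0.65, camera adjusted p = 0.147. The growth factor Fgf8 fell (-1.71 ± 0.22) and Aldh1a2, an enzyme of retinoic acid synthesis, rose (1.64 ± 0.41, and 1.06 without E9.5 replicate 3), a call that ended in the fit of these 2 stages alone (edgeR adjusted p = 0.0533). For the core cardiac transcription factors 1 of 13 rose and 4 fell (1 and 4 adjusted over the list alone), median -0.23, camera adjusted p = 0.0790, and without E8.5 replicate 3 they were called lower (camera adjusted p = 0.0350, and adjusted p = 0.630 with an estimated correlation over all libraries). The largest falls there were in Myocd, the co-activator of serum response factor (-1.04 ± 0.22, and -0.77 ± 0.17 with the span adjustment), and Mef2c (-0.77 ± 0.14, and -0.42 ± 0.11). The globin share of the libraries was 0.44%, 0.78% and 1.07% at E9.5 beside 0.07% to 0.13% at E8.5.

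Between E9.5 and E14 the largest rises by the fixed rule included muscle, matrix and adult globin genes. The largest falls included RNA-binding regulators, Nodal pathway genes and a primitive globin. Of the 8 largest rises, Ckm, muscle creatine kinase (8.64 ± 0.12), and the calcium pump regulator Sln (8.37 ± 0.40) belong to muscle, Dpt (7.66 ± 0.41) and Col6a6 (7.55 ± 0.19) to the matrix, and Hbb-bt (8.18 ± 0.74) and Hbb-bs (8.14 ± 0.76) to definitive red cells. The others were the prostaglandin synthase Ptgds (8.53 ± 0.37) and the fatty acid-binding protein Fabp4 of capillary endothelium (7.44 ± 0.56). Ckm went from 1.30 ± 0.0914 to 520 ± 30.4 CPM. Of the 8 largest falls, Lin28a (-11.09 ± 0.56) and Trim71 (-5.93 ± 0.19) encode RNA-binding regulators of the let-7 pathway, Tdgf1 and Foxh1 (-9.29 ± 0.44) act in Nodal signalling, and Hbb-bh1 (-7.99 ± 0.51) is a globin of primitive red cells. Tdgf1 had 2 counts over the E14 libraries and 3228 at E9.5, 1420-fold lower with a 95% counting interval of 393 to 11700. The others were the pentraxin Nptx2 (-8.62 ± 0.34), the peptide hormone Cck (-7.66 ± 0.48) and the cartilage and cushion collagen Col2a1 (-5.17 ± 0.17). The highest adjusted p of the 16 genes was 7.27e-06 (edgeR), and Dpt shares its interval in part with Gm32569. In heart muscle Tnnt2 (1.12 ± 0.12), Myh7 (0.90 ± 0.14) and Nppa (1.41 ± 0.21) rose, as did Hand2os1 (0.86 ± 0.22), whereas Isl1 (-2.68 ± 0.17), Nkx2-5 (-1.32 ± 0.13) and Hand2 (-0.56 ± 0.09) fell and Myh6 did not pass (0.06 ± 0.10). Part of Myh7 lies opposite the antisense RNA Mhrt and Hand2 within Gm28063, and their reads cannot be told apart. In all 7334 genes rose and 7082 fell of 28846 (edgeR), with 1145 and 812 long non-coding. Against a log2 fold change of 1 (glmTreat, edgeR) 1871 rose and 985 fell, 70 of the 88 called genes named for it among them.

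Fatty acid oxidation rose as a list. Of its members, 19 of 20 rose, 0 fell and 1 did not pass (19 and 0 adjusted over the list alone). The fatty acid oxidation list had a median log2 fold change of 0.96 and a camera adjusted p = 4.37e-08 (adjusted p = 0.456 with an estimated correlation). The nuclear receptor Ppara (3.76 ± 0.13), the long-chain dehydrogenase Acadl (2.48 ± 0.14) and the fatty acid transporter Cd36 (2.34 ± 0.14) rose the most. Of the oxidative phosphorylation genes, 18 of 20 rose, 0 fell and 2 did not pass (18 and 0 adjusted over the list alone), led by Cox8b (5.23 ± 0.25) and the mitochondrial creatine kinase Ckmt2 (1.5 ± 0.19). The oxidative phosphorylation list had a median of 0.59 and a camera adjusted p = 2.09e-05 (adjusted p = 0.492 with an estimated correlation). Glycolysis and glucose uptake went the other way: 1 of 16 rose, 10 fell and 5 did not pass (1 and 10 adjusted over the list alone), and the glucose transporters Slc2a3 (-2.71 ± 0.43) and Slc2a1 (-2.39 ± 0.09) fell the most. The glycolysis and glucose uptake list had a median of -0.45 and a camera adjusted p = 0.00107 (adjusted p = 0.456 with an estimated correlation). Of the sarcomere genes, 17 of 25 rose, 2 fell and 6 did not pass (17 and 2 adjusted over the list alone). The sarcomere list had a median of 0.58 and a camera adjusted p = 0.00107 (adjusted p = 0.456 with an estimated correlation). The M-band protein Myom2 (6.01 ± 0.33), Myoz2 (3.81 ± 0.33) and the titin cap Tcap (1.44 ± 0.10) rose, and the atrial light chain Myl7 fell (-1.26 ± 0.14). Calcium handling genes were not called as a list: 9 of 20 rose and 4 fell (9 and 4 adjusted over the list alone), median 0.32, camera adjusted p = 0.0704. Beside Sln, the calsequestrin gene Casq2 (6.14 ± 0.23) and Pln (2.98 ± 0.39) rose, and the pacemaker channel Hcn4 fell (-2.75 ± 0.23). Of the cell cycle genes, 0 of 25 rose, 21 fell and 4 did not pass (0 and 22 adjusted over the list alone), with the cyclins Ccne1 (-1.34 ± 0.11) and Ccnb1 (-1.09 ± 0.11) first. The cell cycle list had a median of -0.71 and a camera adjusted p = 2.10e-06 (adjusted p = 0.456 with an estimated correlation). Of the core cardiac transcription factors, 0 of 13 rose, 8 fell and 5 did not pass (1 and 9 adjusted over the list alone). The core cardiac transcription factors list had a median of -0.66 and a camera adjusted p = 0.00180 (adjusted p = 0.486 with an estimated correlation). Gata5 (-3.15 ± 0.15) and Hand1 (-2.55 ± 0.11) fell more than Nkx2-5. For chamber and conduction patterning 5 of 15 rose and 6 fell (5 and 6 adjusted over the list alone), median -0.19, camera adjusted p = 0.727: Tbx3 (-1.94 ± 0.09) and Tbx2 (-1.83 ± 0.20), repressors of the chamber programme, fell and the gap junction gene Gja5 rose (1.71 ± 0.12).

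Several progenitor and signalling lists were called lower over the same interval. Of the second heart field and progenitor genes, 3 of 16 rose, 11 fell and 2 did not pass (3 and 11 adjusted over the list alone). The second heart field and progenitors list had a median log2 fold change of -1.92 and a camera adjusted p = 0.00635 (adjusted p = 0.344 with an estimated correlation). The largest falls were in the growth factors Wnt2 (-4.46 ± 0.24) and Fgf8 (-3.84 ± 0.30). Of the BMP pathway genes, 1 of 16 rose, 13 fell and 2 did not pass (1 and 13 adjusted over the list alone), led by the target Msx2 (-3.97 ± 0.15) and the antagonist Nog (-3.69 ± 0.18). The BMP pathway list had a median of -1.25 and a camera adjusted p = 1.09e-05 (adjusted p = 0.344 with an estimated correlation). Of the Hox genes, 0 of 26 rose, 13 fell and 13 did not pass (0 and 13 adjusted over the list alone), and Hoxa10 (-4.51 ± 1.49) and Hoxa11 (-4.36 ± 1.42) fell the most. Hoxa10 went from 0.732 ± 0.924 to 0.0260 ± 0.0343 CPM, with 1.80 CPM in E9.5 replicate 1, without which the values were -2.66 for Hoxa10 and -2.46 for Hoxa11 and both calls ended. Their calls also ended without E14 replicates 1 and 3, and that of Hoxa11 without E14 replicate 2 (edgeR adjusted p = 0.0536 to 0.148, E9.5 replicate 1 included), and both without a filter on low counts (0.0624 to 0.0776). The Hox genes list had a median of -1.44 and a camera adjusted p = 0.00360 (adjusted p = 0.456 with an estimated correlation). Of the pluripotency and epiblast genes, 2 of 12 rose, 7 fell and 3 did not pass (2 and 8 adjusted over the list alone), with Sall4 (-4.46 ± 0.17) behind Lin28a, Tdgf1 and Trim71. The pluripotency and epiblast list had a median of -1.58 and a camera adjusted p = 5.82e-04 (adjusted p = 0.344 with an estimated correlation). Primitive streak and early mesoderm genes were not called: 2 of 15 rose and 5 fell (2 and 4 adjusted over the list alone), median -1.09, camera adjusted p = 0.0599, and the median was -1.04 with Mesp1 and Cdx2, which had 0 counts at E14, at their bound. Of the endoderm and epithelium genes, 1 of 14 rose, 9 fell and 4 did not pass (1 and 10 adjusted over the list alone). The endoderm and epithelium list had a median of -2.91 and a camera adjusted p = 0.00260 (adjusted p = 0.530 with an estimated correlation). The claudin Cldn6 (-6.09 ± 1.38) and the keratin Krt8 (-4.43 ± 0.26) fell, and the gut hormone Pyy had 1 count over the E14 libraries and 79 at E9.5, 69.6-fold lower with a 95% counting interval of 12.1 to 2780.

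Lists of other cell types changed between E9.5 and E14. Of the fibroblast and matrix genes, 14 of 18 rose, 1 fell and 3 did not pass (14 and 1 adjusted over the list alone). The fibroblast and matrix list had a median log2 fold change of 2.28 and a camera adjusted p = 4.08e-06 (adjusted p = 0.344 with an estimated correlation). Elastin, Eln (6.52 ± 0.35), the collagen Col6a3 (4.47 ± 0.30) and the proteoglycan Dcn (4.26 ± 0.31) rose the most, and Eln went from 0.876 ± 0.315 to 81.0 ± 27.5 CPM. Of the macrophage and leukocyte genes, 12 of 14 rose, 0 fell and 2 did not pass (12 and 0 adjusted over the list alone). The macrophage and leukocyte list had a median of 2.01 and a camera adjusted p = 7.83e-05 (adjusted p = 0.389 with an estimated correlation), led by the complement genes C1qc (4.94 ± 0.48) and C1qa (4.67 ± 0.58). Of the epicardium genes, 5 of 11 rose, 1 fell and 5 did not pass (7 and 1 adjusted over the list alone), with the mesothelial surface proteins Msln (5.53 ± 0.60) and Muc16 (5.03 ± 0.38) first. The epicardium list had a median of 1.34 and a camera adjusted p = 0.0182 (adjusted p = 0.546 with an estimated correlation). Of the endothelium and endocardium genes, 11 of 18 rose, 1 fell and 6 did not pass (11 and 1 adjusted over the list alone), with the tight junction gene Cldn5 (2.76 ± 0.25) and the sialomucin Emcn (1.59 ± 0.16) at the top. The endothelium and endocardium list had a median of 0.52 and a camera adjusted p = 0.00163 (adjusted p = 0.456 with an estimated correlation). Of the somite and skeletal muscle genes, 7 of 10 rose, 0 fell and 3 did not pass (7 and 1 adjusted over the list alone); beside Ckm, which heart muscle expresses as well, the homeobox factor Meox2 (5.39 ± 0.34) and the myogenic factor Myog (4.21 ± 0.65) rose. The somite and skeletal muscle list had a median of 2.59 and a camera adjusted p = 0.00360 (adjusted p = 0.456 with an estimated correlation). The primitive erythroid globins fell together: 0 of 3 rose, 3 fell and 0 did not pass (0 and 3 adjusted over the list alone). The primitive erythroid globins list had a median of -3.61 and a camera adjusted p = 0.0199 (adjusted p = 0.456 with an estimated correlation). The erythroid list was split: 5 of 14 rose and 7 fell (5 and 7 adjusted over the list alone), median -0.95, mean 0.30, camera adjusted p = 0.317, the median and mean differing in sign. The adult globins Hbb-bt and Hbb-bs rose and the erythroid factor Klf1 fell (-4.70 ± 0.29). The globin share varied between the E14 libraries, from 1.91% in replicate 2 to 6.03% in replicate 3.

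**Figure D3:**
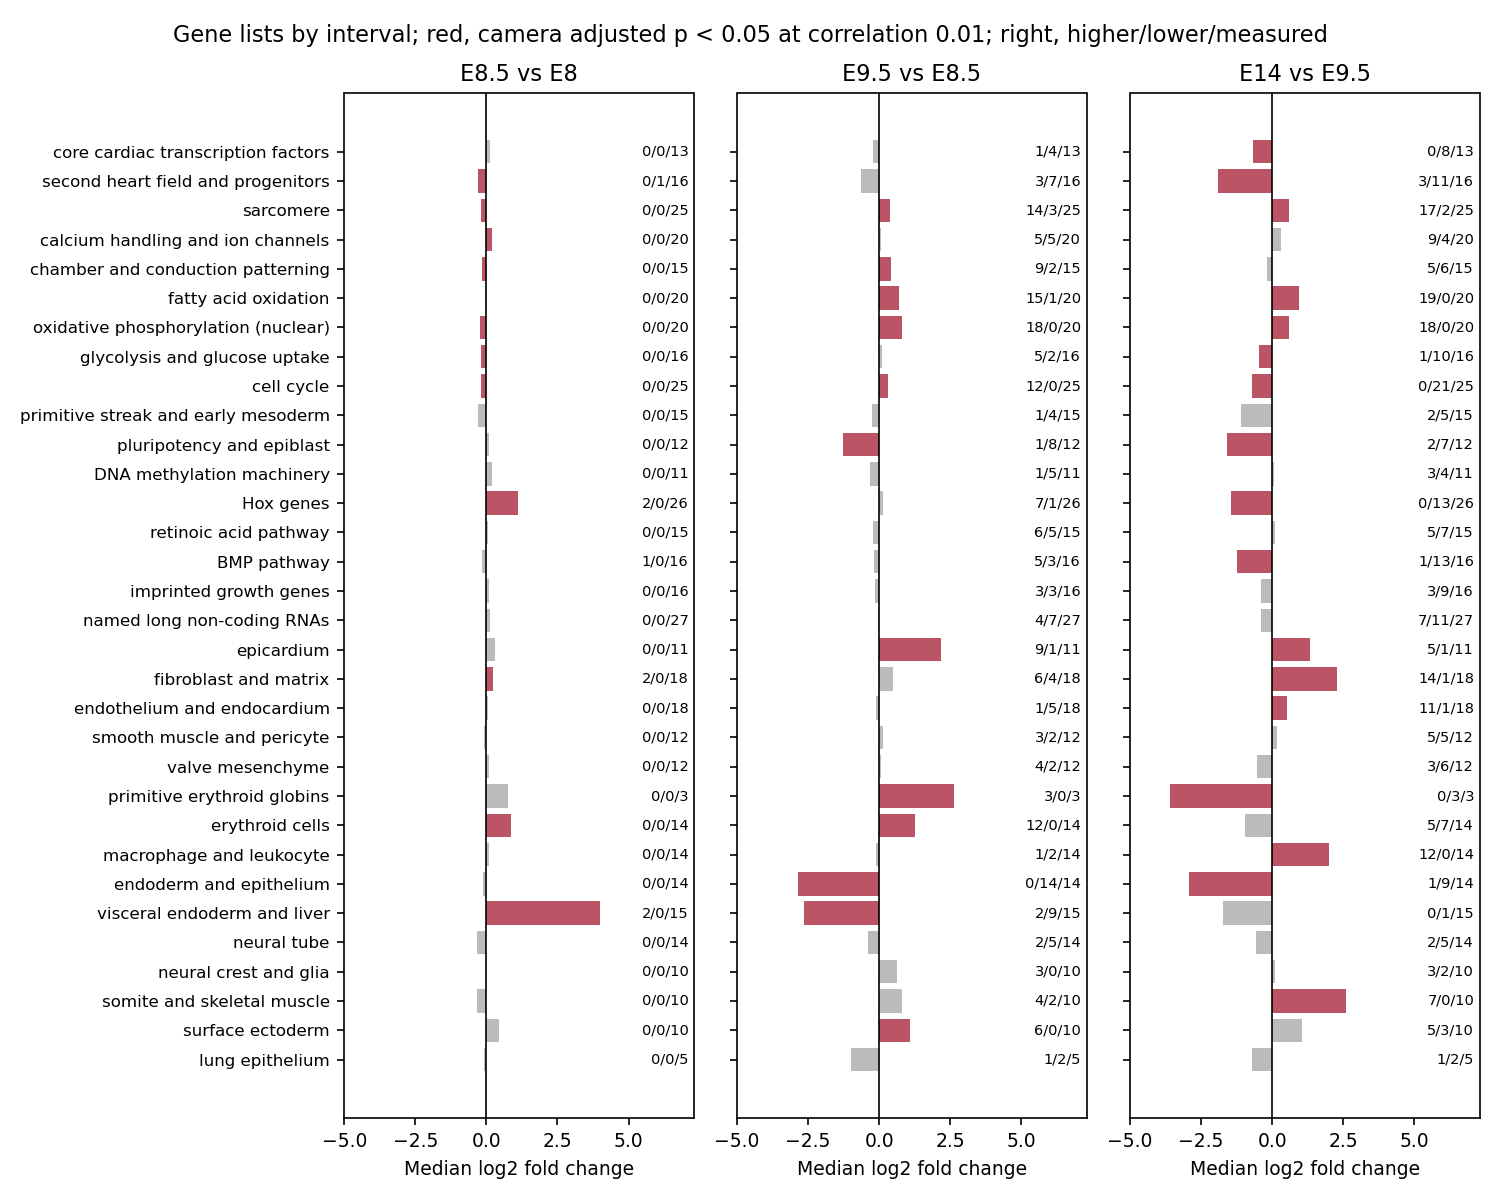
Median log2 fold change (x axes, bars) of the 32 gene lists (y axis) over the 3 intervals, with red bars for lists called by camera at an adjusted p under 0.05 and a preset correlation of 0.01, and the numbers of members higher, lower and measured at the right of each panel. Fatty acid oxidation has medians of 0.68 for E9.5 against E8.5 and 0.96 for E14 against E9.5.

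Over the whole span from E8 to E14, among sarcomere genes Myoz2 (7.17 ± 0.40), Myom2 (5.65 ± 0.31) and Myl2 (2.83 ± 0.21) rose the most, and Tnnt2 (1.26 ± 0.12) and Myh7 (1.30 ± 0.14) rose too. Casq2 rose by 7.56 ± 0.25 to 416 ± 26.5 CPM, Nppa by 2.65 ± 0.22 and Hand2os1 by 1.21 ± 0.22. Calcium handling genes were not called as a list: 9 of 20 rose and 3 fell (9 and 3 adjusted over the list alone), median 0.19, camera adjusted p = 0.0954. Dcn (8.36 ± 0.40) and Eln (7.84 ± 0.38) led the matrix genes. Fgf8 (-5.94 ± 0.30), Wnt2 (-5.01 ± 0.25) and Isl1 (-4.04 ± 0.17) fell among progenitor genes, and Gata5 (-3.65 ± 0.15), Hand1 (-2.33 ± 0.11), Nkx2-5 (-1.79 ± 0.13) and Hand2 (-0.50 ± 0.09) among cardiac factors. Trim71 (-7.20 ± 0.20) and Sall4 (-5.74 ± 0.18) fell as well. The highest adjusted p of these genes was 5.17e-04 (edgeR), while Myh6 (0.17 ± 0.10) and T (-0.94 ± 0.41) did not pass, though T was called in 4 of the alternatives. In all 9089 genes rose and 8410 fell of 28846 (edgeR), and 5932 and 5619 of these were protein-coding. By glmTreat (edgeR) 19 of the 24 called genes named for it were called. Tested over the 4 stages together, 20858 genes differed (edgeR), and of these 4223 had their highest mean at E8, 4421 at E8.5, 3712 at E9.5 and 8502 at E14. Xist (0.69 ± 0.28, edgeR adjusted p = 0.0480) and Ddx3y (0.46 ± 0.17, edgeR adjusted p = 0.0380) were both higher at E14, and Eif2s3y did not pass (0.13 ± 0.14, edgeR adjusted p = 0.441). Between E9.5 and E14 Ddx3y (0.83 ± 0.17, edgeR adjusted p = 0.00191) and Eif2s3y (0.36 ± 0.14, 0.0457) rose, the latter a call that ended in 14 of the alternatives, and Xist did not pass (-0.05 ± 0.28). Between E8 and E8.5 none of the 3 passed, but without E8.5 replicate 3 Xist rose (1.20 ± 0.18) and Ddx3y (-0.53 ± 0.12) and Eif2s3y (-0.72 ± 0.14) fell (highest edgeR adjusted p = 0.00610). The call of Xist between E8 and E14 ended without E8 replicate 2 or 3, E8.5 replicate 1 or any E9.5 or E14 library (edgeR adjusted p = 0.0508 to 0.143) and with the span adjustment (0.0536), RLE (0.0530) or upper-quartile factors (0.0515) or no filter (0.112). That of Ddx3y ended without any E8 or E14 library (edgeR adjusted p = 0.0596 to 0.206), with 0.29 without E14 replicate 1, and with RLE factors (0.0513), no filter (0.0760) or small structural RNAs left out (0.0519).

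Every fatty acid oxidation and oxidative phosphorylation gene measured was higher at E14 than at E8. Of the first list, 20 of 20 rose, 0 fell and 0 did not pass (20 and 0 adjusted over the list alone). The fatty acid oxidation list had a median log2 fold change of 1.65 and a camera adjusted p = 5.96e-09 (adjusted p = 0.410 with an estimated correlation). Of the second, 20 of 20 rose, 0 fell and 0 did not pass (20 and 0 adjusted over the list alone). The oxidative phosphorylation list had a median of 1.19 and a camera adjusted p = 1.13e-07 (adjusted p = 0.456 with an estimated correlation). Of the sarcomere genes, 18 of 25 rose, 2 fell and 5 did not pass (18 and 2 adjusted over the list alone). The sarcomere list had a median of 0.75 and a camera adjusted p = 6.36e-04 (adjusted p = 0.456 with an estimated correlation). Of the fibroblast and matrix genes, 15 of 18 rose, 2 fell and 1 did not pass (15 and 2 adjusted over the list alone). The fibroblast and matrix list had a median of 3.19 and a camera adjusted p = 7.05e-05 (adjusted p = 0.344 with an estimated correlation). Of the epicardium genes, 10 of 11 rose, 1 fell and 0 did not pass (10 and 1 adjusted over the list alone). The epicardium list had a median of 4.43 and a camera adjusted p = 7.04e-04 (adjusted p = 0.456 with an estimated correlation). Of the macrophage and leukocyte genes, 12 of 14 rose, 1 fell and 1 did not pass (12 and 1 adjusted over the list alone). The macrophage and leukocyte list had a median of 2.79 and a camera adjusted p = 0.00144 (adjusted p = 0.456 with an estimated correlation). Of the somite and skeletal muscle genes, 7 of 10 rose, 2 fell and 1 did not pass (7 and 2 adjusted over the list alone). The somite and skeletal muscle list had a median of 3.48 and a camera adjusted p = 0.0220 (adjusted p = 0.456 with an estimated correlation). Of the surface ectoderm genes, 7 of 10 rose, 2 fell and 1 did not pass (8 and 2 adjusted over the list alone). The surface ectoderm list had a median of 2.41 and a camera adjusted p = 0.0369 (adjusted p = 0.530 with an estimated correlation). Without E8.5 replicate 3 that list had a camera adjusted p = 0.0537.

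Other lists were lower at E14 than at E8. Of the BMP pathway genes, 1 of 16 rose, 14 fell and 1 did not pass (1 and 14 adjusted over the list alone). The BMP pathway list had a median log2 fold change of -1.42 and a camera adjusted p = 1.09e-05 (adjusted p = 0.344 with an estimated correlation). Of the second heart field and progenitor genes, 3 of 16 rose, 13 fell and 0 did not pass (3 and 13 adjusted over the list alone). The second heart field and progenitors list had a median of -2.93 and a camera adjusted p = 0.00109 (adjusted p = 0.344 with an estimated correlation). Of the core cardiac transcription factors, 1 of 13 rose, 10 fell and 2 did not pass (1 and 10 adjusted over the list alone). The core cardiac transcription factors list had a median of -0.83 and a camera adjusted p = 0.00107 (adjusted p = 0.456 with an estimated correlation). Of the glycolysis and glucose uptake genes, 4 of 16 rose, 10 fell and 2 did not pass (4 and 10 adjusted over the list alone). The glycolysis and glucose uptake list had a median of -0.69 and a camera adjusted p = 0.0112 (adjusted p = 0.533 with an estimated correlation). Of the cell cycle genes, 1 of 25 rose, 17 fell and 7 did not pass (1 and 18 adjusted over the list alone). The cell cycle list had a median of -0.54 and a camera adjusted p = 0.00123 (adjusted p = 0.565 with an estimated correlation). Of the primitive streak and early mesoderm genes, 1 of 15 rose, 10 fell and 4 did not pass (1 and 12 adjusted over the list alone). The primitive streak and early mesoderm list had a median of -1.69 and a camera adjusted p = 0.00504 (adjusted p = 0.456 with an estimated correlation). Of the pluripotency and epiblast genes, 1 of 12 rose, 8 fell and 3 did not pass (1 and 8 adjusted over the list alone). The pluripotency and epiblast list had a median of -2.25 and a camera adjusted p = 0.00144 (adjusted p = 0.407 with an estimated correlation). Of the endoderm and epithelium genes, 0 of 14 rose, 13 fell and 1 did not pass (0 and 14 adjusted over the list alone). The endoderm and epithelium list had a median of -5.42 and a camera adjusted p = 3.26e-06 (adjusted p = 0.456 with an estimated correlation). Among the lists not called, Hox genes (median 0.05, mean -0.25), smooth muscle and pericyte (0.05 and -0.04) and visceral endoderm and liver (-0.42 and 0.10) had a median and a mean of opposite sign.

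Fold changes of long non-coding RNAs were correlated with those of coding genes transcribed divergently from them, the arrangement that yylncT, the RNA of the series title, has with the Brachyury gene. Gata5os and Gata5 fell together between E8 and E14 (-3.75 ± 0.13 and -3.65 ± 0.15), as did Gm13061 and Lin28a (-10.97 ± 0.55 and -12.81 ± 0.57), Gm29202 and the RNA-binding protein gene Igf2bp1 (-2.50 ± 0.17 and -2.48 ± 0.09) and Gm43109 and the adhesion molecule gene Vcam1 (-1.31 ± 0.09 and -1.32 ± 0.08). Rbm46os and Rbm46 rose together (6.04 ± 0.31 and 2.73 ± 0.14). The highest adjusted p of these 10 genes was 1.44e-07 (edgeR). In GRCm38 the non-coding partners lie at chromosome 2, 180332857 to 180340732 (Gata5os), chromosome 4, 134018147 to 134019869 (Gm13061), chromosome 11, 96005889 to 96008055 (Gm29202), chromosome 3, 116128451 to 116141016 (Gm43109) and chromosome 3, 82876705 to 82943638 (Rbm46os), all on the plus strand. All but Rbm46os overlap their partner, by 52 to 1843 bp, where reads of the pair cannot be told apart without strand. Across 1085 such pairs (starts at most 2000 bp apart) the Spearman correlation was 0.293 for E8.5 against E8, 0.404 for E9.5 against E8.5, 0.560 for E14 against E9.5 and 0.546 for E14 against E8. Pearson's r was 0.356, 0.552, 0.701 and 0.696 in the same order. Each two-sided permutation p was 1e-05, the smallest possible (1.33e-05 for Spearman and 1.6e-05 for Pearson adjusted over 8 correlations of each kind). With the nearest coding gene on the other side of the same RNAs (1083 pairs) the Spearman correlation was 0.12, 0.129, 0.190 and 0.170, and the highest adjusted permutation p was 9.00e-05. Not matched for distance, this control does not isolate the arrangement. In the 488 pairs whose intervals do not overlap, the Spearman correlation was 0.121 (permutation p = 0.00710), 0.209, 0.445 and 0.409, the first beside 0.12 with the gene on the other side. Overlapping pairs included, 383 of the 466 pairs with both genes called between E8 and E14 moved the same way and 83 opposite ways. Between E8.5 and E9.5 they were 126 and 23 of 149. Between E8 and E8.5 0 pairs had both called by edgeR (81 at an unadjusted p under 0.05, and 34 by DESeq2). These correlations are across genes, which are not independent replicates.

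**Figure D4:**
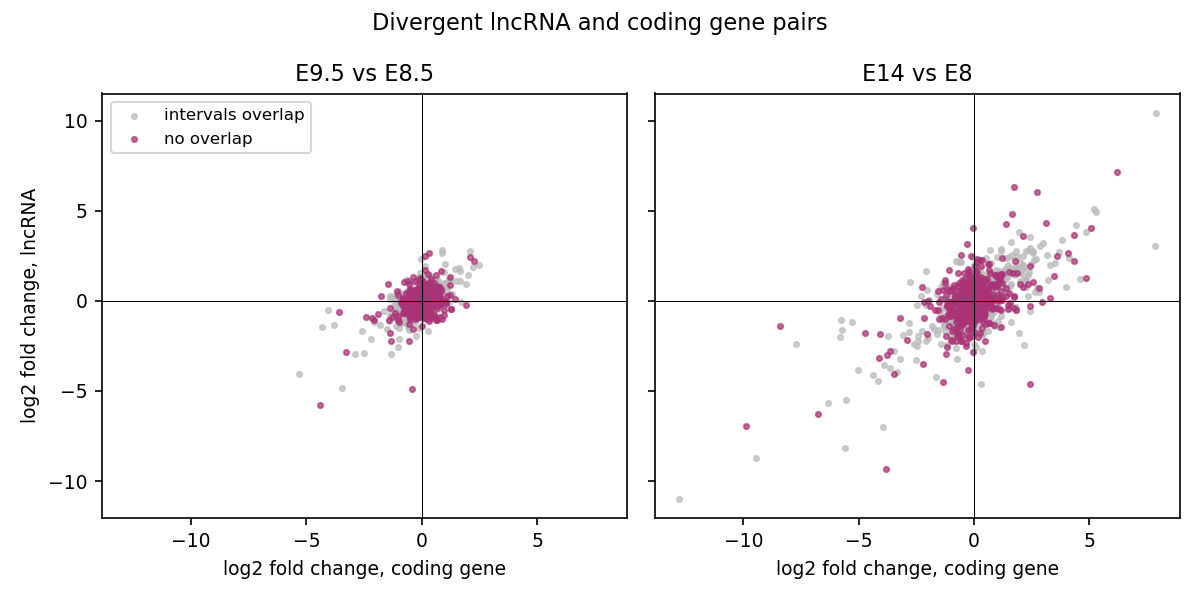
Log2 fold change of long non-coding RNAs (y axis) against that of the coding gene transcribed divergently (x axis), with 1 point per pair, for E9.5 against E8.5 and E14 against E8, in grey where the intervals of a pair overlap and in purple where they do not. Points spread along the diagonal, with Spearman correlations of 0.404 and 0.546.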

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

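Settings on span, small structural RNAs and overlaps were chosen after seeing the data. The comparison of E8.5 with E8 moved the most. Genes higher and lower in it numbered 146 and 44 without a filter on low counts, 903 and 661 with a minimum of 1 CPM in 3 libraries, 3 and 6 in a fit of these 2 stages alone (5794 at an unadjusted p under 0.05), and 2361 and 2075 by DESeq2. They were 69 and 49 with the span adjustment, of which 68 and 33 were among the 257 and 84 called without it, 78 and 38 over intervals without overlap, 659 and 480 with small structural RNAs left out and 2804 and 4443 with the span adjustment and without E8.5 replicate 3. Against a log2 fold change of 1 (glmTreat, edgeR) 0 and 0 genes were called (410 at an unadjusted p under 0.05). With 1 library left out the counts ran from 0 to 4212 and from 0 to 4653, with 0 and 0 in edgeR without E8 replicate 3 (5398 at an unadjusted p under 0.05). In the later comparisons glmTreat called 198 and 183 for E9.5 against E8.5, 1871 and 985 for E14 against E9.5 and 3264 and 2013 for E14 against E8. Over intervals without overlap, where fewer genes were tested, the counts were 2601 and 2101, 3061 and 3276 and 3801 and 3891 in the same order, and 8942 genes differed over the 4 stages. A fit of the 2 stages alone gave 3353 and 2746 for E9.5 against E8.5. With 1 library left out that comparison had 3628 to 6968 higher and 3366 to 6047 lower, E14 against E9.5 6089 to 7916 and 6112 to 8369, and E14 against E8 7919 to 9587 and 7539 to 9587. Fewer samples, fewer genes tested or a larger fold to exceed are part of some of these settings, and beyond that the cause was not tested.

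Of the 128 list tests 56 were called at the preset correlation and 0 by camera with an estimated correlation, where the smallest adjusted p was 0.344 and 13 had an unadjusted p under 0.05. With 1 library left out 51 to 62 were called. Over 2428 recomputed list results 2319 kept their direction and call, 80 lost and 28 gained a call, and the median of the endothelium and endocardium list for E8.5 against E8 turned to -0.0982 with the span adjustment. Of 235 gene results named, 204 were called, and of 5717 recomputed values 5237 kept direction and call, 419 lost it and 60 gained one. Dnmt3b for E8.5 against E8 turned to -0.335 with the span adjustment and without E8.5 replicate 3. In every setting but glmTreat in which they were tested 0 of 22 named calls held for E8.5 against E8, 59 of 70 for E9.5 against E8.5, 82 of 88 for E14 against E9.5 and 22 of 24 for E14 against E8, and glmTreat called 0, 25, 70 and 19 of them. The rank correlation of divergent pairs between E8 and E14 was 0.409 to 0.546 over the settings run for it, each with the smallest permutation p. The causes of these changes were not tested. Depth limits what can be said of genes with few counts, such as T with 2 to 9 counts per library at E9.5.

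With the replicate number as a block, 2 and 1 genes were called higher and lower for E8.5 against E8 in edgeR (7577 at an unadjusted p under 0.05), 25 of the named genes lost their call and 0 lists did. The numbers did not pair the libraries: over 18 same-numbered pairs the correlation of deviations from the stage means ran from -0.0836 to 0.134, with 1 above 0.1, and 4 of the 12 libraries correlated best with their own number. The block moved no other count of calls by over 1.5 times.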

Other observations

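The 8 lists not described above were called by camera in none of the comparisons, and no member of them passed edgeR's test between E8 and E8.5. In the retinoic acid pathway 6 of 15 rose and 5 fell (6 and 5 adjusted over the list alone) between E8.5 and E9.5, when Aldh1a1, an enzyme of retinoic acid synthesis, rose (5.63 ± 1.0) and Cyp26a1, which degrades retinoic acid, fell (-2.50 ± 0.35). Between E9.5 and E14 5 of 15 rose and 7 fell (5 and 7 adjusted over the list alone), and the binding protein gene Crabp2 (-4.29 ± 0.20) and the retinol uptake receptor gene Stra6 (-3.54 ± 0.20) fell. Its median and mean had opposite signs in both intervals (-0.21 and 0.22, then 0.08 and -0.66). Of the valve mesenchyme genes 4 of 12 rose and 2 fell (5 and 2 adjusted over the list alone) between E8.5 and E9.5, with Sox9 (1.93 ± 0.33) and Twist1 (1.44 ± 0.22) first. Between E9.5 and E14 3 of 12 rose and 6 fell (3 and 6 adjusted over the list alone), and Has2 (-3.63 ± 0.17) and Hapln1 (-3.43 ± 0.17), which make and link the hyaluronan of the cardiac jelly, fell the most. Of the smooth muscle and pericyte genes 3 of 12 rose and 2 fell (3 and 2 adjusted over the list alone) between E8.5 and E9.5, where the potassium channel subunit Abcc9 rose (1.40 ± 0.20) and the smooth muscle myosin Myh11 fell (-0.89 ± 0.22). Between E9.5 and E14 5 of 12 rose and 5 fell (6 and 5 adjusted over the list alone), with a median of 0.18 and a mean of -0.03, and the channel gene Kcnj8 rose (6.25 ± 0.24) and Lmod1 fell (-4.71 ± 0.19). Of the imprinted growth genes 3 of 16 rose and 3 fell (3 and 6 adjusted over the list alone) and then 3 of 16 rose and 9 fell (4 and 9 adjusted over the list alone) in these 2 intervals. Phlda2 fell in both (-2.08 ± 0.42 and -5.50 ± 0.68), H19 rose in the first (0.77 ± 0.16) and Peg10 fell in the second (-1.61 ± 0.20). The lowest camera adjusted p over the 4 comparisons was 0.529 for retinoic acid, 0.0687 for valve mesenchyme, 0.209 for smooth muscle and 0.161 for imprinted genes, and the highest edgeR adjusted p of the genes named as rising or falling was 0.00854.

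Of the named long non-coding RNAs 4 of 27 rose and 7 fell (5 and 7 adjusted over the list alone) between E8.5 and E9.5, and 7 of 27 rose and 11 fell (7 and 11 adjusted over the list alone) between E9.5 and E14. Dnm3os, a host transcript of microRNAs, rose (3.63 ± 0.73) and Six3os1 fell (-2.93 ± 0.50) in the first. In the second Hoxa11os had 0 counts at E14 and 45 at E9.5, at least 13.2-fold lower against a floor of 3 counts over the group, and Lhx1os (-3.61 ± 0.61) and Fendrr (-3.15 ± 0.49), a regulator of lateral mesoderm, fell. Of the neural tube genes 2 of 14 rose and 5 fell (2 and 6 adjusted over the list alone) and then 2 of 14 rose and 5 fell (2 and 5 adjusted over the list alone) in the same intervals. The forebrain factor Otx2 fell in both (-3.60 ± 0.42 and -4.37 ± 0.82), Six3 fell in the first (-3.34 ± 0.84) and Zic1 rose in the second (4.16 ± 0.74). Of the neural crest and glia genes 3 of 10 rose and 0 fell (3 and 0 adjusted over the list alone), with Tfap2b first (3.65 ± 0.84), and then 3 of 10 rose and 2 fell (4 and 2 adjusted over the list alone), with Tfap2b falling (-2.24 ± 0.79). Of the lung epithelium genes 1 of 5 rose and 2 fell (1 and 2 adjusted over the list alone) and 1 of 5 rose and 2 fell (1 and 2 adjusted over the list alone), and Irx1 (-1.16 ± 0.15 and -1.20 ± 0.16) and Etv5 (-1.0 ± 0.11 and -0.95 ± 0.12) fell in both. The lowest camera adjusted p over the 4 comparisons was 0.253 for the long non-coding RNAs, 0.147 for neural tube, 0.0951 for neural crest and 0.170 for lung epithelium, and the highest edgeR adjusted p of the genes named as rising or falling was 0.0333. Fendrr lies within Gm20388, whose count was 3461 times its own, and Hoxa11os, Six3, Dnm3os and Zic1 overlap genes with 0.795 to 2.76 times theirs, where reads cannot be told apart. Phlda2 stood at -1.27 between E8.5 and E9.5 without E8.5 replicate 3. The fall of Myh11 lost its call with the span adjustment and without E8.5 replicate 3 (edgeR adjusted p = 0.0920). The call of Hoxa11os ended without E9.5 replicate 1 or E14 replicate 2 (edgeR adjusted p = 0.0564 and 0.0532). The fall of Tfap2b between E9.5 and E14 lost its call without E9.5 replicate 2 or 3 or E14 replicate 2 or 3 (edgeR adjusted p = 0.0514 to 0.221) and in a fit of the 2 stages alone (0.0641), and stood at -1.23 without E9.5 replicate 3.

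Of the tests that follow, those on introns of short hosts, on ratios to hosts and on parent genes were written before their result was seen, and the others (all on E8.5 replicate 3, the span adjustment, introns of long hosts, the pseudogenes within pairs of stages, and the splits) after. E8.5 replicate 3 stood at 0.0681 between the means of E8 (0) and E9.5 (1), beside 0.272 and 0.204 for replicates 1 and 2. An E8 library of the same dissection under the wrong name is argued against by visceral endoderm genes at a median of 5.07 (log2) above the highest E8 library. Visceral endoderm may account for the list's own excess, a median of 3.22 over the highest other E8.5 library. Of its 15 measured genes 0 are in another list and 5 reached 1 CPM in all 3 E8 libraries, and Apob (658 CPM), Cubn (470) and Afp (246) were the most abundant in replicate 3. For the rest, visceral endoderm as the whole cause and embryos of an earlier stage cannot be told apart, and an E8 library with more endoderm under the wrong name was not tested: the library stood 0.136 below the lower of the other 2 (0.0680 apart), which is the pattern itself, and leaving out endoderm genes hardly moved this distance (0.138 with them).

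Coding genes that rose between E8 and E8.5 had a median interval of 104 kb beside 23.3 kb for all tested. With a trend of libraries with gene span removed, 68 of the 257 genes called higher stayed so, and the median log2 fold change of the 257 went from 0.795 (median SE 0.143) to 0.486 (0.12); of the 189 that were no longer called, 158 had a smaller fold and 70 a larger SE. The 46 coding genes then called higher had a median interval of 46.5 kb, which 6 of 10000 random sets of the same mean expression reached, but the 31 called lower had 51.4 kb, so that the trend as the whole cause stays open. A larger share of unspliced RNA in E8.5 replicates 1 and 2 stays open. Genes inside introns of short hosts lay -0.458 (log2) from the highest E8 library, but short genes may lose CPM as long ones gain. Inside introns of long hosts they lay 0.18 above that library. A change in which long genes are transcribed between these stages was not tested and may look the same. The ratio of genes inside introns to their hosts differed by -0.006 and met the bound set beforehand against unspliced RNA. It may decide nothing, because host counts may include the reads of genes inside them.

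Between E8.5 and E9.5, 30 of 2785 processed pseudogenes (1.08%) fell by 3 or more on the log2 scale, beside 0.4% of coding genes, and 22 rose by 3 or more. A fall of the parent genes is argued against by a median difference of -4.34 from the parent over 10 pseudogenes, 9 of which are named as copies of Rps12. Inside the pairs E8 with E8.5 and E9.5 with E14 the larger median change of the 30 was 0.254 in size. Some moved more, such as Gm43897 (6.824 and 3.265) and Gm15235 (0.184 and -2.028). E8 and E8.5 libraries might have been prepared, sequenced or mapped differently from the others. As no label gives a batch this cannot be told from stage.

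Among splits of the same libraries into groups of the same sizes, the real split was the 1 of 10 with the most genes in each pair of stages, and 10 splits are too few for a share under 0.05. The real and highest other counts were 341 and 4 for E8.5 against E8, 10659 and 237 for E9.5 against E8.5, 14416 and 3 for E14 against E9.5 and 17499 and 0 for E14 against E8. Over the 4 stages 1 of 100 splits, the real one, gave as many (20858, and 13589 at most in the others), so that chance assignment of the libraries to stages is unlikely there.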
